A study of Homo sapiens with 17 samples.

How the data were processed

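Messenger RNA was profiled in 17 libraries of B cells isolated from human tonsil. The labels place 3 libraries in the naive group, 3 in the germinal centre (GC) group and 3 in the memory group, and 4 libraries each in the dark zone (DZ) and light zone (LZ) groups, the compartments of the germinal centre. The series' design text calls the GC cells total germinal centre B cells, while the titles of these libraries say CB, an abbreviation of centroblast, and whether they were enriched for centroblasts is not given in the sources used here. Per the labels' protocols, mononuclear cells were prepared on Ficoll and the B cell populations were separated magnetically, the zones by another published procedure than the other populations. The surface markers used for the separation are not given in the sources used here, so a gene that encodes one of them is not an independent finding between the populations. Total RNA was extracted with Trizol and a column, and libraries were made with the TruSeq RNA v2 kit, which does not mark the strand. Reads from a gene and from an overlapping gene on the other strand therefore cannot be told apart.

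The deposited table holds TPM values, transcript abundances scaled to a fixed total, as the authors' file name in the labels says, and each of the 17 columns sums to 1000000.0. The submitters' processing notes name CASAVA 1.8, HISAT2 without a version, SAMtools 1.8 and the GRCh38 build. The annotation release and the program that counted reads are not given in the sources used here. The table has 47878 entries, 1 for each gene symbol, with a location on GRCh38. For 138 symbols the location spans more than 3000000 bases, which means that several loci carry the same symbol and were merged. The 35 genes of the mitochondrial chromosome are listed at 0 in every library, so 0 above 0 were found in any library, and no value is reported for them. Genes with near-identical copies, such as those encoding the IgG heavy chains, can share reads, and their single values are uncertain.

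TPM values carry no depth of their own. Multiplying each value by the gene's exonic length in GENCODE 29, available for 46426 symbols, and dividing by the step that 1 read is worth in the library gave an estimate of the reads assigned to genes. The estimate ran from 20.9 to 44.7 M reads (M, 1000000 reads) per library. Of the values that came out under 200 reads, 61.3% to 66.5% lay within 0.02 of a whole number, so the estimates are approximate and were used only to describe depth and in 1 alternative fit. The DZ and LZ libraries held a mean of 37.5 and 36.9 M estimated reads, against 25.0, 26.1 and 23.5 M in the naive, GC and memory libraries.

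The libraries of the 2 separation procedures also differed in composition. Ribosomal RNA loci held 0.986% to 7.28% of TPM in the naive, GC and memory libraries and 0.001% in the DZ and LZ libraries. Nuclear copies of mitochondrial sequence held 2.93% to 4.18% in the former and 4.41% to 6.38% in the latter. Since all genes of the mitochondrial chromosome are listed at 0, it is not known whether reads of that chromosome were assigned to these copies, and the shares cannot be read as their own transcripts. For that reason no gene was tested between the 9 naive, GC and memory libraries and the 8 zone libraries. Pearson correlations between libraries of the same group, across genes on the log2 scale, ran from 0.960 to 0.981, and 0 pairs of libraries had identical values.

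Y-linked, sex-informative and copy-polymorphic genes were removed before any analysis, 550 entries in all. P2RY8 and IL3RA were lost with them, because the table lists them with a location on the Y chromosome. Genes were kept where at least 3 of the 9 naive, GC and memory libraries (18576 genes), or at least 4 of the 8 zone libraries (16717 genes), reached a TPM of 1. Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, by moderated statistics with an intensity trend, two-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05 within each comparison. GC against naive, memory against GC and memory against naive came from 1 fit of the 9 libraries, and LZ against DZ from 1 fit of the 8 zone libraries. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Levels are the mean TPM ± SD. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and drew the plots.

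A set of 32 gene lists was fixed before the data were examined, and 448 of their 450 genes were found in the table. The lists cover naive, memory and GC B cell identity, the dark and light zone markers, NF-kB, immediate early genes, heat shock and handling stress, MHC class II, the cell cycle phases, somatic hypermutation and class switching, homologous recombination, plasma cell genes, the BCL2 family, apoptosis effectors, chemotaxis and adhesion, B cell receptor signalling, chromatin regulators, quiescence, oxidative phosphorylation, glycolysis, MYC targets and ribosome biogenesis, interferon response and the immunoglobulin heavy constant genes. The remaining lists hold markers of T, myeloid, plasmacytoid dendritic, NK, stromal and follicular dendritic, epithelial, and erythroid and platelet cells. Members past the threshold were counted by direction, over all genes and adjusted over the list alone. Each list with at least 3 tested members was set against all other genes with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the residuals. With the estimated correlation 4 calls held. They were GC B identity in GC against naive and in memory against GC, and light zone markers and NF-kB in LZ against DZ. GC B identity and light zone markers are lists of separated populations, so their calls bear first on the separation. Calls were also lost where the estimate lay below 0.01, as for apoptosis effectors in GC against naive (-0.003) and the BCL2 family in LZ against DZ (-0.092). A lost call alone therefore does not show correlation within a list.

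Genes named in the text follow a rule fixed before the data were examined. For each comparison it takes the 5 genes with the largest rise and the 5 with the largest fall among those past the threshold, with every library of 1 group above every library of the other and a mean of at least 10 TPM in the higher group. Immunoglobulin, T cell receptor, clone-named and antisense genes and pseudogenes are left out of that choice. Added to these are a fixed set of anchor genes and, for each list described, up to 3 members with the smallest adjusted p. Any other gene was named after its values were seen, as an example of a list's members or of a marker.

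The tests were tried on simulated data with known answers, in which 200 genes were changed by 1.5, 2 or 4-fold. For GC against naive (17605 simulated genes) 20.9%, 38.8% and 74.2% of the changed genes were recovered at these sizes. For memory against GC (17588 genes) the shares were 14.9%, 58.2% and 83.3%. For memory against naive (17602 genes) they were 7.5%, 46.3% and 51.5%, and for LZ against DZ (16083 genes) 9%, 52.2% and 87.9%. Between 5 and 10 unchanged genes were called in a comparison, and 0 changed genes were called in the wrong direction. In this simulation a 1.5-fold change was therefore missed more often than found. In the real comparisons, in the same order, 50%, 46.7%, 9.2% and 28.7% of the tested genes passed, far more than were changed here. The Benjamini-Hochberg cutoff is looser where more genes change, so the simulated shares may understate what the real tests recovered.

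The series' design text says that naive, GC and memory cells came from 3 independent donors each and the zones from 4 donors each. The p-values therefore rest on the spread between donors' samples within a group, each sample with 1 library. In the unblocked zone fit that spread includes donor differences that paired libraries share. Whether equal replicate numbers mark the same donor was checked from the correlation of residuals around the group means. For DZ and LZ all 4 same-numbered pairs correlated, with r from 0.481 to 0.543, against -0.319 to -0.01 for the 12 other pairs, so the numbers pair the zone libraries, and a fit with the number as a block was run beside the unblocked one. The same-numbered naive, GC and memory libraries showed no such correlation and were not treated as paired.

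Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM, quantile normalization, median-ratio scaling, rescaling without immunoglobulin, mitochondrial and ribosomal protein genes, limma without the trend, 1 fit over all 17 libraries, the replicate block, a 2-fold minimum, and leaving out each library. Chosen after seeing the data were limma voom on the estimated reads, rescaling without ribosomal RNA loci and nuclear mitochondrial copies, and leaving out DZ and LZ replicate 2 together. Corrections for GC content or gene length were not applied, and a bias of that kind that differs between libraries was not tested.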

Results

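Transcript levels were measured in naive, total germinal centre and memory B cells and in B cells of the dark and light zones of human tonsil. Naive B cells have not met antigen. Germinal centre B cells divide and mutate their antibody genes, in the dark zone, and are selected by antigen and T cell help, in the light zone. Memory B cells are among the products of that selection. There were 3 libraries each of naive, GC and memory cells and 4 each of DZ and LZ cells, with 20.9 to 44.7 M estimated reads (M, 1000000 reads) per library. Between 15591 and 17616 genes reached a TPM of 1 in a library. All adjusted p-values are from limma, and levels are mean TPM ± SD with n = 3 for naive, GC and memory cells and n = 4 for DZ and LZ cells.

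The comparison of GC with naive cells asked which genes mark entry into the germinal centre reaction. Most tested genes of GC B identity, of cell division and of hypermutation and class switching were higher in GC cells, and most chemotaxis and adhesion receptor, interferon response and MHC class II genes were lower. Of these lists only GC B identity kept its camera call with an estimated correlation. SERPINA9, a serpin gene of germinal centre B cells (chromosome 14, 94462717 to 94476333, protein coding), had 669 ± 181 TPM in GC and 2.42 ± 1.55 TPM in naive cells, a log2 fold change of 7.67 (SE 0.49, adjusted p = 2.71e-06). S1PR1, the receptor for exit from lymphoid tissue (chromosome 1, 101236888 to 101241518), had 2.01 ± 0.945 TPM in GC and 199 ± 59.9 TPM in naive cells, and its log2 fold change was -6.06 (SE 0.42, adjusted p = 3.87e-06).

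Among 18576 genes tested, 5443 were higher and 3841 lower in GC cells, so 58.6% of the calls were higher. Under quantile normalization the split was 4657 higher and 4965 lower (48.4% higher), and the median log2 fold change of all genes moved from 0.06 to -0.06. In 59.5% of the genes the 3 GC libraries did not overlap the 3 naive libraries, where chance gives 10%. The other genes with the largest rises were MME, which encodes CD10, the G protein regulator RGS13, FDCSP and EML6, at 77.2, 76.8, 71.4 and 67.5-fold. Next to S1PR1, the largest falls were in COL19A1, SPRY1, PARP15 and KLF2, at log2 fold changes of -5.50, -5.45, -5.32 and -5.27. KLF2 encodes a transcription factor that activates S1PR1.

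Of the 21 GC B identity genes, 20 rose and none fell, over all genes and adjusted over the list alone (camera adjusted p = 2.67e-11, and 0.0444 with an estimated correlation). SUGCT reached 85.1 ± 11.8 TPM from 0.479 ± 0.209, MYBL1 366 ± 25.1 from 5.30 ± 0.601, and BCL6, the repressor that directs the germinal centre state, 440.1 ± 16.1 from 47.3 ± 10.6 TPM (log2 fold change 3.22, adjusted p = 2.11e-05). Dark zone markers rose in 9 of 12 genes and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 9.79e-05). That call was lost at adjusted p = 0.159 with an estimated correlation. NUGGC, a dark zone marker, rose 65.0-fold, and the member that fell was CXCR4, at 750.5 ± 156 TPM in GC and 1792 ± 421 TPM in naive cells.

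All 21 tested genes of G2/M and mitosis and all 20 of G1/S and DNA replication rose, also adjusted over the list alone (camera adjusted p = 7.96e-13 and 1.80e-12). With an estimated correlation the adjusted p = 0.28 and 0.228. The proliferation marker MKI67 rose from 9.52 ± 1.82 to 289 ± 55.3 TPM (log2 fold change 4.78, adjusted p = 5.04e-06), and CCNB1, KIF20A and CDK1, which drive or carry out mitosis, rose 17, 22.7 and 31.8-fold. In somatic hypermutation and class switching, 15 of 18 genes rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 5.31e-05, and adjusted p = 0.228 with an estimated correlation). The mismatch repair genes MSH6 and EXO1 rose 3.32 and 10.4-fold and RPA1, which coats single-stranded DNA, 2.94-fold, while APEX1 was the gene that fell. Homologous recombination and replication stress genes rose in 13 of 15 cases and none fell, over all genes and adjusted over the list alone (camera adjusted p = 7.12e-07, and adjusted p = 0.228 with an estimated correlation).

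Apoptosis effectors rose in 10 of 16 genes and 1 fell, against 13 and 1 adjusted over the list alone (camera adjusted p = 0.00373, and adjusted p = 0.159 with an estimated correlation). The BH3-only genes BIK and HRK rose 26.1 and 10.1-fold, and CASP8 fell. BCL2, which blocks apoptosis, fell from 27.1 ± 4.18 to 1.73 ± 0.295 TPM (log2 fold change -3.36, adjusted p = 1.83e-06). The other 4 tested survival members of its family, MCL1, BCL2L1, BCL2A1 and BCL2L2, rose, with the same counts adjusted over the list alone (camera adjusted p = 0.193). In oxidative phosphorylation 19 of 23 genes rose and none fell, against 20 and 0 adjusted over the list alone (camera adjusted p = 1.08e-05, and adjusted p = 0.28 with an estimated correlation). Under quantile normalization 12 of the 23 genes rose, and under voom 13 of the 19 tested there.

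Naive B markers fell in 9 of 13 genes and 1 rose, against 10 and 1 adjusted over the list alone (camera adjusted p = 5.47e-05, and adjusted p = 0.31 with an estimated correlation). FCMR, the IgM receptor gene, fell from 1143 ± 283 to 53.8 ± 8.04 TPM and FCER2, which encodes CD23, from 888 ± 322 to 42.7 ± 7.58 TPM (adjusted p = 1.26e-06 and 0.000141). BACH2, a repressor of plasma cell differentiation, was the member that rose. Chemotaxis and adhesion receptors fell in 10 of 17 genes and rose in 3, with the same counts adjusted over the list alone (camera adjusted p = 0.00202, and adjusted p = 0.226 with an estimated correlation). CCR6 fell 31.7-fold, while S1PR2, which confines B cells to the germinal centre, rose 21.2-fold.

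Interferon response genes fell in 13 of 18 cases and 1, RSAD2, rose, with the same counts adjusted over the list alone (camera adjusted p = 1.29e-05, and adjusted p = 0.348 with an estimated correlation). IFI44, IFI44L and IFIT2 fell 20.2, 16.6 and 6.33-fold. MHC class II presentation genes fell in 11 of 12 cases and none rose, against 12 and 0 adjusted over the list alone (camera adjusted p = 4.25e-05, and adjusted p = 0.228 with an estimated correlation). HLA-DOA was at 248 ± 13.9 TPM in GC and 594 ± 105 TPM in naive cells. HLA-DPA1 (chromosome 6, 33064569 to 33080710) and HLA-DPB1 (33075926 to 33087201) fell 2.98 and 3.20-fold, but they overlap on opposite strands and their reads cannot be fully told apart. Quiescence genes fell in 8 of 13 cases and rose in 1, and immediate early genes fell in 7 of 14 and rose in 3, each with the same counts adjusted over the list alone. Their camera adjusted p = 0.0034 and 0.0188, and with an estimated correlation the adjusted p = 0.226 for both.

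Several markers of other cell types were also higher in the GC libraries. T cell markers rose in 13 of 15 genes and CD5, which B cells also express, fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000755, and adjusted p = 0.436 with an estimated correlation). PDCD1 and ICOS, genes of follicular helper T cells, and the list member CXCL13 had 15.0 ± 6.06, 5.79 ± 2.42 and 23.9 ± 19.2 TPM in GC libraries. In naive libraries they had 1.0 ± 0.404, 0.149 ± 0.212 and 0.786 ± 0.445 TPM. Which cells the CXCL13 transcripts came from was not tested. The higher zone mean was 0.7146 of the GC mean for PDCD1 and 0.0283 for ICOS, so PDCD1 may also be expressed by the B cells. Of 4 tested stroma and follicular dendritic cell markers 3 rose and CR1, which B cells also express, fell from 191 ± 9.63 to 40.0 ± 4.48 TPM, with the same counts adjusted over the list alone (camera adjusted p = 0.198). FDCSP, itself among the largest rises above, varied from library to library, at 173 ± 116 TPM, as did CLU at 105 ± 83.8 TPM. Plasmacytoid dendritic cell markers rose in 4 of 6 genes, among them GZMB at 13.7 ± 1.95 TPM in GC and 2.56 ± 1.30 TPM in naive libraries, and LILRA4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.236). None of the GC against naive genes named by the rule lost its call when a library was left out.

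**Figure D1:**
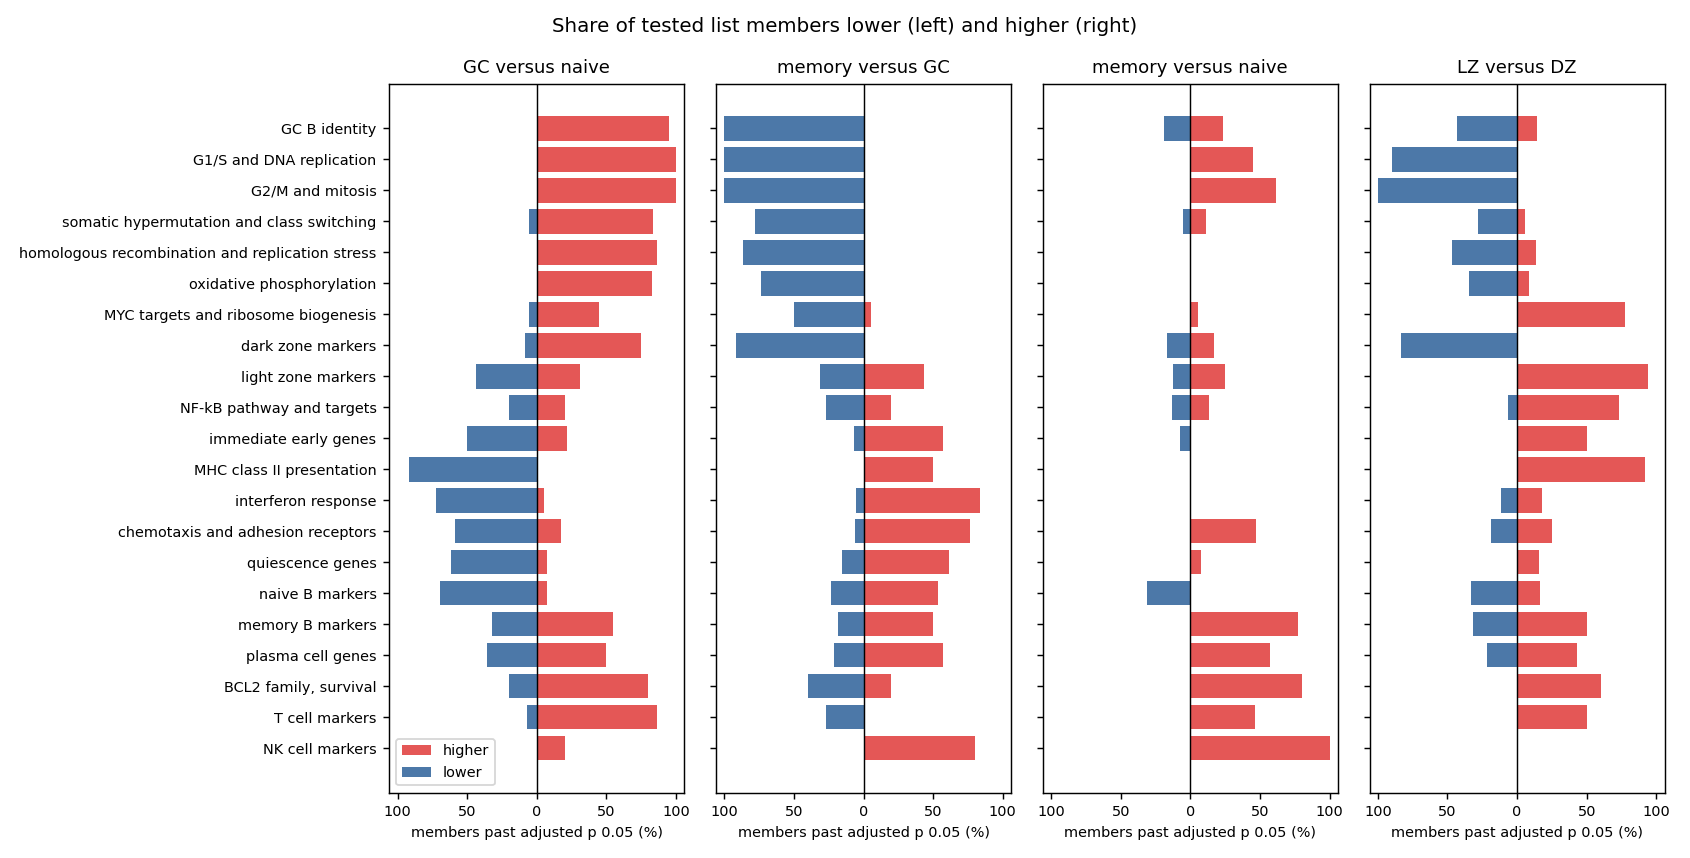
Percent of the tested members of 21 gene lists past an adjusted p of 0.05 in each of the 4 comparisons, with lower genes drawn to the left in blue and higher genes to the right in red. The cell cycle lists reach 100% to the right in GC against naive and 100% to the left in memory against GC, and light zone markers reach 15 of 16 genes to the right in LZ against DZ.

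The comparison of memory with GC cells asked what changes as cells leave the reaction. All tested GC B identity and cell division genes were lower in memory cells, and most, though not all, chemotaxis and adhesion receptor, quiescence and interferon response genes were higher. Of these lists only GC B identity kept its camera call with an estimated correlation. TNFRSF13B, which encodes the cytokine receptor TACI (chromosome 17, 16933065 to 16972118), rose from 2.20 ± 0.470 to 302 ± 77.1 TPM, a log2 fold change of 6.54 (SE 0.24, adjusted p = 3.24e-07). MME (chromosome 3, 155024124 to 155183729) fell from 164 ± 4.36 to 0.827 ± 0.289 TPM, a log2 fold change of -6.51 (SE 0.17, adjusted p = 1.61e-07). BCL2 rose from 1.73 ± 0.295 to 40.6 ± 9.74 TPM (log2 fold change 3.91, adjusted p = 1.21e-06).

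In memory cells 4064 genes were higher and 4619 lower (46.8% higher). The balance turned to 4600 higher and 4200 lower (52.3% higher) after rescaling without immunoglobulin, mitochondrial and ribosomal protein genes, and to 4674 and 4148 (53% higher) under voom. Their libraries did not overlap those of GC cells in 59.6% of genes, where chance gives 10%. TBC1D27 rose 88.7-fold, but its locus (chromosome 17, 16922915 to 16934839) overlaps that of TNFRSF13B on the same strand, and the reads of the 2 may not be separable. BHLHE41, the chemokine receptor gene CCR1 and KLF2 rose 56.6, 49.4 and 46.9-fold. The largest falls after MME were in MYBL1, FDCSP, SUGCT and CLU, at log2 fold changes of -6.30, -6.09, -5.83 and -5.77. FDCSP and CLU are the genes whose GC levels varied between libraries. The higher of their zone means was 0.0295 and 0.0202 of the GC mean. RNA of follicular dendritic cells in the GC libraries may account for the falls of FDCSP and CLU, as described below.

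All 21 GC B identity genes fell, also adjusted over the list alone (camera adjusted p = 2.44e-13, and 0.0257 with an estimated correlation). BCL6 fell 13.9-fold. Dark zone markers fell in 11 of 12 genes and none rose, against 11 and 1 adjusted over the list alone (camera adjusted p = 2.07e-06, and adjusted p = 0.0643 with an estimated correlation). The G2/M genes fell in 21 of 21 cases and the G1/S genes in 20 of 20, also adjusted over the list alone (camera adjusted p = 5.79e-13 and 1.37e-12, and adjusted p = 0.295 and 0.238 with an estimated correlation). NUSAP1, a spindle protein gene, fell from 357 ± 52.6 to 31.6 ± 10.9 TPM, and CCNB1 and KIF20A fell 9.37 and 11.8-fold.

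Hypermutation and class switching genes fell in 14 of 18 cases and homologous recombination genes in 13 of 15, and none rose, with the same counts adjusted over each list alone (camera adjusted p = 2.45e-06 and 1.00e-07). With an estimated correlation the adjusted p = 0.207 for both. Oxidative phosphorylation genes fell in 17 of 23 cases and none rose, also adjusted over the list alone (camera adjusted p = 4.73e-06, and adjusted p = 0.295 with an estimated correlation), with 13 falls under quantile normalization and 11 among the 19 genes tested under voom. MYC targets and ribosome biogenesis genes fell in 9 of 18 cases and rose in 1, against 10 and 1 adjusted over the list alone (camera adjusted p = 0.0124, and adjusted p = 0.529 with an estimated correlation).

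Interferon response genes rose in 15 of 18 cases and RSAD2 fell, with the same counts adjusted over the list alone (camera adjusted p = 4.86e-07, and adjusted p = 0.295 with an estimated correlation). IFI44, IFIT2 and OAS2 rose 14, 7.29 and 3.67-fold. Chemotaxis and adhesion receptors rose in 13 of 17 genes and 1, S1PR2, fell, against 14 and 1 adjusted over the list alone (camera adjusted p = 5.24e-06, and adjusted p = 0.11 with an estimated correlation). CCR6 had 262 ± 42.7 TPM in memory and 6.04 ± 0.668 TPM in GC cells, and S1PR4 138 ± 27.0 and 17.7 ± 3.17 TPM. Quiescence genes rose in 8 of 13 cases and 2, TOB1 and CCNG2, fell, against 9 and 2 adjusted over the list alone (camera adjusted p = 0.00216, and adjusted p = 0.207 with an estimated correlation). CDKN1B, which encodes a cell cycle inhibitor, and FOXO3 rose 2.85 and 2.52-fold.

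Memory B markers rose in 11 of 22 genes and 4 fell, against 12 and 5 adjusted over the list alone (camera adjusted p = 0.00818, and adjusted p = 0.529 with an estimated correlation). GPR183, a guidance receptor gene, rose 24.6-fold. The 4 that fell were CD27, CD80, SOX5 and TOX. CD27 had 293 ± 76.8 TPM in memory and 434 ± 16.6 TPM in GC cells (log2 fold change -0.60, adjusted p = 0.0297). That call was lost without GC replicate 1, 2 or 3 or memory replicate 1, at adjusted p = 0.0845, 0.0655, 0.0638 and 0.0739, and under quantile normalization at 0.106. PRDM1, the plasma cell regulator gene, rose from 3.78 ± 0.524 to 18.6 ± 8.30 TPM (adjusted p = 0.00686).

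MHC class II genes rose in 6 of 12 cases and none fell, also adjusted over the list alone (camera adjusted p = 0.00362, and adjusted p = 0.36 with an estimated correlation), and voom gave 10 rises. Naive B markers rose in 7 of 13 genes and fell in 3, against 8 and 3 adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.529 with an estimated correlation). Immediate early genes rose in 8 of 14 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 0.0178, and adjusted p = 0.207 with an estimated correlation). NK cell markers rose in 4 of 5 tested genes and none fell, also adjusted over the list alone (camera adjusted p = 0.0116, and adjusted p = 0.36 with an estimated correlation). T cell markers fell in 4 of 15 genes and none rose, also adjusted over the list alone (camera adjusted p = 0.229).

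The comparison of memory with naive cells asked how the resting populations before and after antigen encounter differ. Memory libraries had more transcript of most memory markers, of most switched immunoglobulin constant genes and of several plasma cell genes, and less of TCL1A and some other naive markers. None of these lists kept its camera call with an estimated correlation. NK cell markers and part of the T cell markers were also higher in the memory libraries, as given below. Whether RNA of other cells contributed to the rises in this comparison was not tested. CD27, a TNF receptor family gene that marks memory cells (chromosome 12, 6444867 to 6451718), had 293 ± 76.8 TPM in memory and 24.6 ± 4.53 TPM in naive cells, a log2 fold change of 3.50 (SE 0.19, adjusted p = 0.000178). AIM2, the DNA sensor gene (chromosome 1, 159062484 to 159076901), rose from 13.7 ± 2.6 to 226 ± 78.4 TPM (log2 fold change 3.90, SE 0.24, adjusted p = 0.000178). TCL1A, an AKT coactivator gene (chromosome 14, 95709967 to 95714196), had 224 ± 186 TPM in memory and 1156 ± 219 TPM in naive cells (log2 fold change -2.68, SE 0.47, adjusted p = 0.00945).

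Here 1410 genes were higher and 308 lower in memory cells, 82.1% higher, and 25.9% of genes had libraries that did not overlap, where chance gives 10%. The split was 1065 and 646 (62.2% higher) under quantile normalization and 1167 and 524 (69% higher) under median-ratio scaling, and the median of all genes moved from 0.06 to -0.06 and -0.003. Without naive replicate 1 the counts were 811 and 126, without naive replicate 3 873 higher, without memory replicate 2 891 and 153, and the lower genes numbered 144 without naive replicate 2 and 191 without memory replicate 3.

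The largest rises were in CCR1 at 114 ± 97.5 TPM from 2.40 ± 0.816, the calcium-binding protein gene TESC, BTNL9, and the entries MIAT_exon5_2 and MIAT_exon5_1. These last are segments of a long non-coding RNA on chromosome 22 (26672164 to 26672248 and 26671402 to 26671550). They rose 27.5, 26.3, 21.9, 26.4 and 21.4-fold in that order. The largest falls were in the chemokine gene CCL3, which has near-identical copies, TCL1B, TCL6, TCL1A and P2RY14, at log2 fold changes of -3.48, -3.00, -2.74, -2.68 and -2.63. TCL1B, TCL6 and TCL1A are neighbours on chromosome 14.

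Memory B markers rose in 17 of 22 genes and none fell, against 19 and 0 adjusted over the list alone (camera adjusted p = 8.00e-18, and adjusted p = 0.129 with an estimated correlation). CD80, which encodes a T cell costimulator, and TNFRSF13B rose 7.31 and 9.86-fold. Immunoglobulin heavy constant genes rose in 6 of 9 cases, against 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.75e-05, and adjusted p = 0.129 with an estimated correlation). IGHG1, IGHG3 and IGHG4 rose 19.2, 8.09 and 16.5-fold, as genes that can share reads. IGHD, the IgD constant gene, was at 704 ± 576 TPM in memory and 2080.0 ± 399.5 TPM in naive cells and missed the threshold (adjusted p = 0.152).

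Plasma cell genes rose in 8 of 14 cases and none fell, against 10 and 0 adjusted over the list alone (camera adjusted p = 1.75e-05, and adjusted p = 0.129 with an estimated correlation). SLAMF7, the secretory regulator XBP1 and the signal peptidase gene SEC11C rose 3.49, 2.46 and 1.74-fold. Survival members of the BCL2 family rose in 4 of 5 cases, against 5 adjusted over the list alone (camera adjusted p = 0.000748, and adjusted p = 0.129 with an estimated correlation). BCL2L2 rose 2.13-fold (adjusted p = 0.0037), and BCL2A1 and BCL2L1 1.61 and 1.45-fold (adjusted p = 0.0248 and 0.0404). The call of BCL2A1 was lost without naive replicate 2 or 3 or memory replicate 2, at adjusted p = 0.0701, 0.0692 and 0.0761. That of BCL2L1 was lost without naive replicate 2 or 3 or memory replicate 1, 2 or 3, at 0.0889, 0.0886, 0.0687, 0.125 and 0.0681. BCL2 itself was at 40.6 ± 9.74 and 27.1 ± 4.18 TPM (adjusted p = 0.124).

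Apoptosis effectors rose in 5 of 16 genes, against 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0076, and adjusted p = 0.129 with an estimated correlation). Chemotaxis and adhesion receptors rose in 8 of 17 genes, against 8 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0316, and adjusted p = 0.376 with an estimated correlation). G2/M genes rose in 13 of 21 cases and G1/S genes in 9 of 20, and none fell, against 20 and 13 adjusted over the lists alone (camera adjusted p = 4.45e-09 and 2.50e-06, and adjusted p = 0.453 for both with an estimated correlation). CENPA, CDC20 and CDK1 rose 3.25, 2.81 and 2.45-fold, and 4, 5 and 8 G2/M genes passed under quantile normalization, median-ratio scaling and voom. CDC20 lost its call without naive replicate 1 or 3 (adjusted p = 0.0713 and 0.0586). CDK1 lost it without naive replicate 1 or 3 or memory replicate 1 or 2 (adjusted p = 0.0814, 0.0577, 0.056 and 0.0697).

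Naive B markers fell in 4 of 13 genes and none rose, against 8 and 0 adjusted over the list alone (camera adjusted p = 2.50e-06, and adjusted p = 0.329 with an estimated correlation). ABCB1, a transporter gene, fell 4.08-fold, IL4R 2.83-fold and FCER2 4.12-fold (adjusted p = 0.0123, 0.0261 and 0.0439). FCER2 lost its call without naive replicate 1, 2 or 3 (adjusted p = 0.128, 0.115 and 0.0514). IL4R lost it without naive replicate 1 or 2 or memory replicate 2 or 3 (adjusted p = 0.0742, 0.0637, 0.0858 and 0.0714). Of the 12 MHC class II genes 0 passed the threshold in limma, over all genes, adjusted over the list alone or by voom, and 2 had an unadjusted p under 0.05, though camera placed the list lower (adjusted p = 0.000178, and adjusted p = 0.329 with an estimated correlation). MYC targets and ribosome biogenesis genes had 1 rise among 18, also adjusted over the list alone, while camera placed them lower (adjusted p = 0.044, and adjusted p = 0.624 with an estimated correlation).

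NK cell markers rose in 5 of 5 tested genes, also adjusted over the list alone (camera adjusted p = 1.03e-05, and adjusted p = 0.179 with an estimated correlation). GNLY, the granulysin gene of cytotoxic cells, had 30.9 ± 9.39 TPM in memory and 0.799 ± 0.985 TPM in naive libraries, and NKG7 and KLRF1 rose 6.36 and 2.77-fold. T cell markers rose in 7 of 15 genes, against 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000131, and adjusted p = 0.453 with an estimated correlation). PDCD1, CD3E and CD2 were at 21.8 ± 5.97, 16.1 ± 8.85 and 7.60 ± 3.37 TPM in memory libraries. PDCD1 transcripts were also found in the zone libraries, so they may not come from T cells alone. Plasmacytoid dendritic cell markers rose in 1 of 6 genes, against 3 adjusted over the list alone (camera adjusted p = 0.0316, and adjusted p = 0.453 with an estimated correlation).

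**Figure D2:**
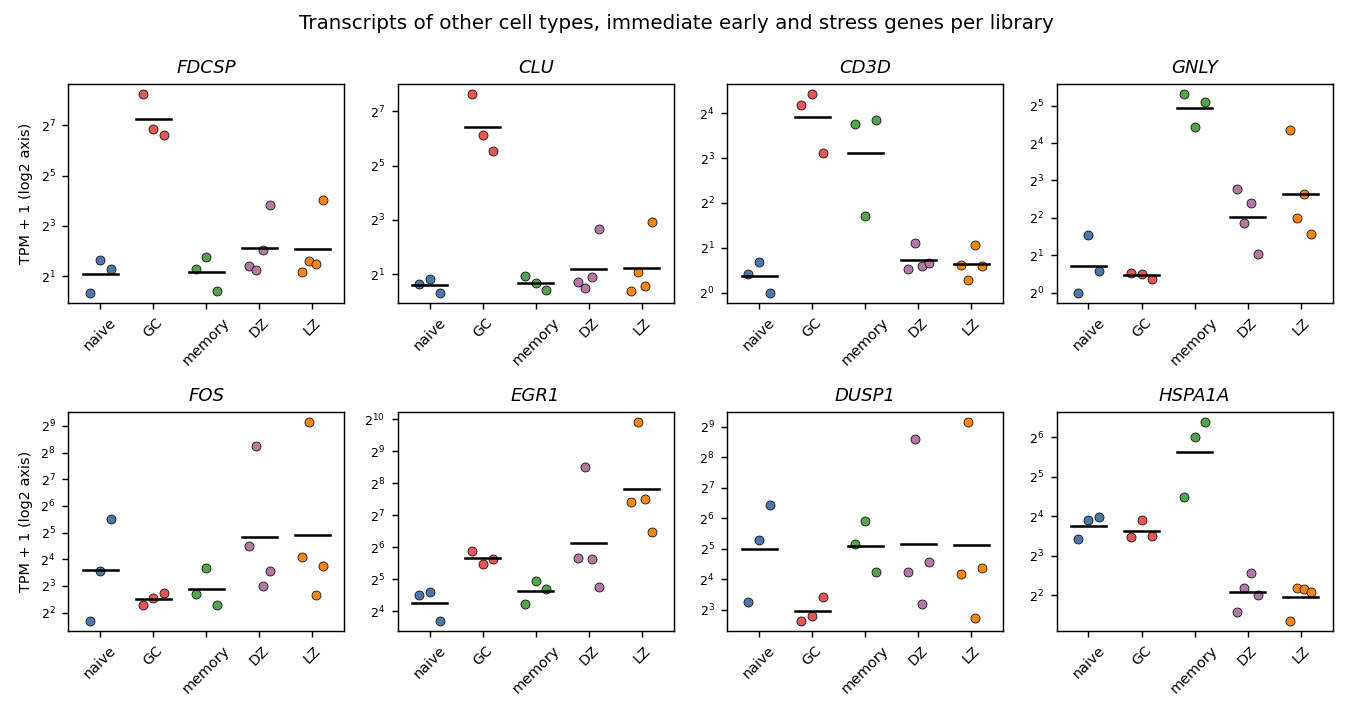
TPM of marker genes of other cell types (CD3D, CLU, FDCSP and GNLY), of immediate early genes (EGR1 and FOS) and of heat shock and handling stress genes (DUSP1 and HSPA1A) in each library on a log2 axis of TPM + 1, with 1 point per library grouped by population and a black line at the geometric mean of TPM + 1. FDCSP and CLU are highest in the total GC libraries, and GNLY is highest in the memory libraries.

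The comparison of the zones asked how GC cells in the light zone differ from those in the dark zone. LZ cells had more transcript of most light zone markers, NF-kB pathway and target genes, MHC class II genes and MYC targets, and less of the mitotic genes. Of these lists the light zone markers and NF-kB kept their camera call with an estimated correlation. Light zone markers were likely beforehand to be higher in cells isolated as light zone cells, so their rise bears on the separation. Whether CD83 or CXCR4 was used to separate the zones is not given in the sources used here. EBI3, a cytokine subunit gene (chromosome 19, 4229498 to 4237531), rose from 3.41 ± 1.06 TPM in DZ to 266 ± 45.8 TPM in LZ cells, a log2 fold change of 5.94 (SE 0.19, adjusted p = 3.76e-06). CD83, an activation marker gene (chromosome 6, 14117256 to 14136918), rose from 192 ± 35.2 to 1346 ± 60.2 TPM (log2 fold change 2.82, SE 0.13, adjusted p = 9.27e-06). CXCR4, which holds cells in the dark zone (chromosome 2, 136114349 to 136118165), had 191 ± 148 TPM in LZ and 1103 ± 330 TPM in DZ cells (log2 fold change -2.88, SE 0.57, adjusted p = 0.00572).

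Of 16717 genes 3011 were higher and 1782 lower in LZ cells, 62.8% higher, in the fit without the replicate block. With the block, which takes the pairing into account, 4309 were higher and 2633 lower. Values of this comparison are from the unblocked fit unless the block is named. That fit treats the paired libraries as independent, and it called fewer genes. List members past the threshold were not counted with the block, and more of them may pass there. In 32.9% of genes the zones did not overlap, where chance gives 2.86% if the pairing is ignored. Without the block the split was 2466 and 2510 (49.6% higher) under quantile normalization and 2479 and 2435 (50.4% higher) under median-ratio scaling. The median of all genes moved from 0.11 to -0.003 and 0.02. After EBI3 the largest rises were in the chemokine gene CCL22, GNG8, MIR155HG, the host gene of a microRNA, and TNFRSF18, at 19.9, 17.6, 17.2 and 15.4-fold. Among the largest falls were those in KANK2, ECEL1, SUGCT and BMP7, at log2 fold changes of -3.98, -3.92, -3.30 and -3.26.

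Light zone markers rose in 15 of 16 genes and none fell, also adjusted over the list alone (camera adjusted p = 3.67e-13, and 0.0157 with an estimated correlation). SLAMF1 rose 8.35-fold, and CD86, a T cell costimulator gene, from 66.9 ± 12.2 to 103 ± 15.8 TPM (adjusted p = 0.019). The call of CD86 was lost without LZ replicate 1 or 3 (adjusted p = 0.0542 and 0.0547). NF-kB pathway and target genes rose in 11 of 15 cases and LTB fell, against 13 and 1 adjusted over the list alone (camera adjusted p = 3.11e-08, and 0.0157 with an estimated correlation). NFKB2, NFKBIE and TRAF1 rose 5.51, 3.85 and 2.39-fold. MHC class II genes rose in 11 of 12 cases, also adjusted over the list alone (camera adjusted p = 2.89e-05, and adjusted p = 0.426 with an estimated correlation). CIITA, the master regulator of that class, rose from 115 ± 39.1 to 426 ± 28.8 TPM, HLA-DQB1 3.33-fold and CD74 1.81-fold, the last with adjusted p = 0.00159, and 0.0725 without the filter on low values.

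MYC rose from 28 ± 12.8 to 116 ± 45.8 TPM (log2 fold change 2.01, adjusted p = 0.00429). MYC targets and ribosome biogenesis genes rose in 14 of 18 cases and none fell, against 15 and 0 adjusted over the list alone (camera adjusted p = 8.80e-09, and adjusted p = 0.358 with an estimated correlation). The ribosome assembly genes PPAN, RRP12 and RRP9 rose 4.42, 3.28 and 2.74-fold. Survival members of the BCL2 family rose in 3 of 5 cases, also adjusted over the list alone (camera adjusted p = 0.00379, and adjusted p = 0.161 with an estimated correlation). BCL2A1 went from 31.3 ± 5.46 to 438 ± 97.0 TPM, BCL2L1 rose 2.70-fold, and BCL2 was at 2.94 ± 0.475 and 0.913 ± 0.326 TPM. Immediate early genes rose in 6 of 12 cases and none fell, also adjusted over the list alone (camera adjusted p = 0.0242, and adjusted p = 0.718 with an estimated correlation). EGR3, DUSP2 and EGR2, induced by receptor signalling, rose 10.7, 8.18 and 7.79-fold, and in replicate 2 of both zones the immediate early genes lay above the other libraries by a median log2 difference of 2.06.

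All 21 G2/M genes fell, and 18 of 20 G1/S genes fell, against 21 and 19 adjusted over the lists alone (camera adjusted p = 2.01e-18 and 7.46e-13, and adjusted p = 0.26 for both with an estimated correlation). AURKA, CCNB2 and CCNB1 fell to 22.8 ± 5.99, 43.7 ± 10.4 and 53.1 ± 11.7 TPM from 108 ± 12.3, 192 ± 19.1 and 202 ± 22.0 TPM. Dark zone markers fell in 10 of 12 genes and none rose, also adjusted over the list alone (camera adjusted p = 6.02e-10, and adjusted p = 0.161 with an estimated correlation). The transcription factor genes TCF3 and FOXO1 were among them, with log2 fold changes of -1.48 and -0.90 (adjusted p = 9.97e-05 and 0.0015), and MME fell from 152 ± 33.5 to 36.0 ± 5.17 TPM.

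GC B identity genes fell in 9 of 21 cases and rose in 3, against 12 and 3 adjusted over the list alone and 13 falls under median-ratio scaling (camera adjusted p = 0.000354, and adjusted p = 0.374 with an estimated correlation). LMO2, RGS13 and KLHL6 were the genes that rose, LMO2 from 132 ± 13.2 to 531 ± 27.5 TPM. BCL6 was at 462 ± 53.2 TPM in LZ and 574 ± 84.0 TPM in DZ cells and missed the threshold (adjusted p = 0.106), which it passed without DZ replicate 4 (0.0469) and under median-ratio scaling (0.0462). Homologous recombination genes fell in 7 of 15 cases and rose in 2, against 8 and 2 adjusted over the list alone (camera adjusted p = 0.00186, and adjusted p = 0.548 with an estimated correlation). Hypermutation and class switching genes fell in 5 of 18 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 0.0165, and adjusted p = 0.548 with an estimated correlation).

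Oxidative phosphorylation genes fell in 8 of 23 cases and rose in 2, against 9 and 2 adjusted over the list alone (camera adjusted p = 0.00573, and adjusted p = 0.551 with an estimated correlation). Without replicate 2 of both zones that list was at adjusted p = 0.0696. Naive B markers fell in 4 of 12 genes and rose in 2, also adjusted over the list alone (camera adjusted p = 0.0306, and adjusted p = 0.548 with an estimated correlation). Immunoglobulin heavy constant genes had 1 fall among 9, also adjusted over the list alone, at a camera adjusted p = 0.0563, and 0.00165 with the replicate number as a block. Plasmacytoid dendritic cell markers had 0 of 3 tested genes past the threshold in limma and by voom, against 3 lower at an unadjusted p under 0.05 and adjusted over the list alone, with a camera adjusted p = 0.0776, and 0.0312 with the block. Stroma and follicular dendritic cell, NK cell and epithelial markers each had 2 tested genes, and in limma 0 passed the threshold, by voom 0, and 0 had an unadjusted p under 0.05.

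**Figure D3:**
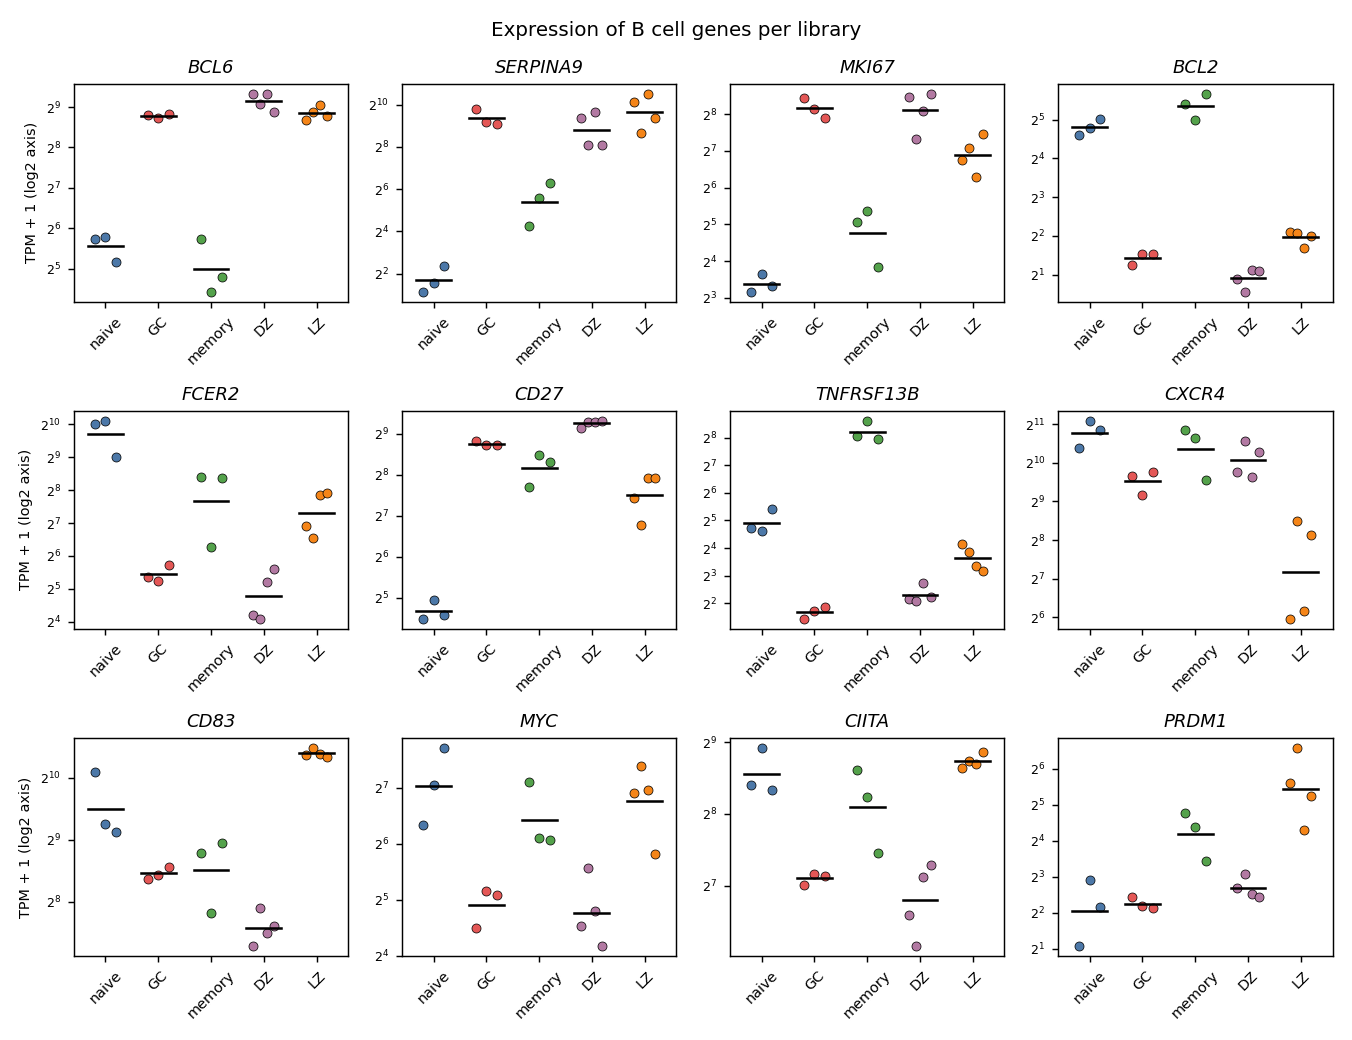
TPM of selected genes in each of the 17 libraries on a log2 axis of TPM + 1, with 1 point per library grouped by population and a black line at the geometric mean of TPM + 1. BCL6 is high in GC, DZ and LZ libraries, CD83 is high in LZ libraries, and TNFRSF13B is high in memory libraries.

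To ask how many genes that differ between GC and naive cells also differ between the zones, calls of the 2 fits were compared. The comparison covered the 16274 genes tested in both. It depends on the naive cells as well, so it cannot by itself place total GC cells between the zones. The GC libraries are titled CB, an abbreviation of centroblast, the dark zone cell. Whether they were enriched for centroblasts is not given in the sources used here, and such an enrichment would by itself bring them closer to DZ cells. Of the genes higher in GC than in naive cells, 1269 were also higher in DZ than in LZ cells, where independent lists would share 562.5, and 645 were higher in LZ cells, where they would share 945.7. Of the genes lower in GC cells, 116 were higher in DZ and 969 higher in LZ cells, against 344.2 and 578.8. With a 2-fold minimum in both, the genes higher in GC and in LZ cells numbered 143 against 141 expected, so that count was no longer below it. On an axis made of the 591 genes at least 2-fold higher in DZ cells minus the 945 at least 2-fold higher in LZ cells, in mean log2(TPM + 1), naive libraries lay at -1.08 ± 0.04, memory libraries at -0.93 ± 0.12 and total GC libraries at 1.11 ± 0.17. DZ and LZ libraries, which defined the axis, lay at 1.85 ± 0.14 and -1.17 ± 0.24. The position of the naive, memory and total GC libraries was not tested, because the separation procedure differed between the 2 sets of libraries. Naive and memory libraries lay near the LZ libraries without being LZ cells, so a position on this axis alone does not show the zone of cells.

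**Figure D4:**
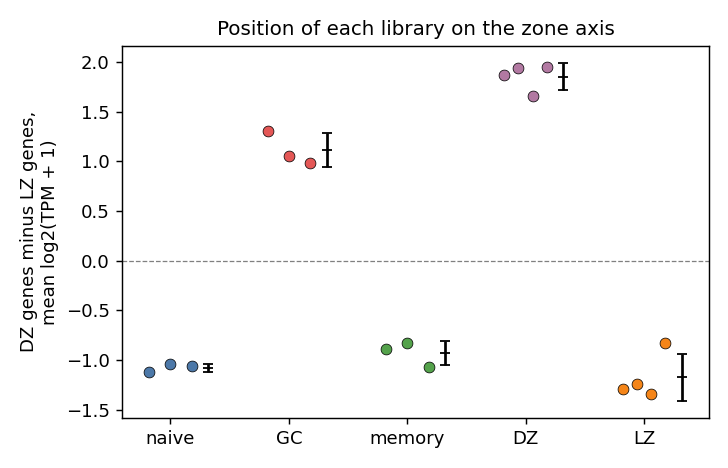
Position of each library on the zone axis, the mean log2(TPM + 1) of genes higher in DZ cells minus that of genes higher in LZ cells, with points for libraries and a bar for the mean ± SD of each population. The 3 total GC libraries lie between 0.98 and 1.30, and the naive and memory libraries lie below 0.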

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

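All tests of explanations and of other groupings of the libraries in this part were chosen after the results they bear on had been seen. In the groups of 4 zone libraries, 38 named genes and 10 library measures were searched in both zones for a library far from the other 3 by Dixon's ratio of the gap to the range, with its 95% critical value for groups of 4. Of the 96 groups 5 passed, and chance alone passes about 1 in 20. DUSP2 in DZ replicate 2 was at 124 TPM against 37.1 to 41.2 in the other DZ libraries (ratio 0.953). EGR2 in DZ replicate 2 was at 60.0 TPM against 10.9 to 18.7 (ratio 0.841). The 10 highest genes held 11.7% of TPM in DZ replicate 2 against 10.2% to 10.3% (ratio 0.946). BCL2L1 in DZ replicate 3 was lowest, at 38.8 TPM against 46.9 to 47.5 (ratio 0.928). SUGCT in LZ replicate 4 was highest, at 25.9 TPM against 6.98 to 9.38 (ratio 0.873).

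DUSP2 and EGR2 belong to the immediate early genes, and 14 of 14 such genes were higher in both libraries of replicate 2 than in every other library of their zone, by a median log2 difference of 1.88 in DZ and 2.28 in LZ and 2.055 over both. An exchange of zone labels in that pair is argued against by its DZ library lying 2.865 above its LZ library on a zone axis made from the other 3 pairs alone. The other pairs, each on an axis made without it, differed by 2.52 to 3.127. A difference in depth is argued against by 2 of its 2 libraries lying within the 28.3 to 44.7 M estimated reads of the others. The 9 heat shock protein and cochaperone genes of the heat shock and handling stress list were higher by a median of 0.478 (median absolute deviation 0.203), too close to the bound of 0.5 set for that test to decide on a heat shock response during handling. The other 5 members, ATF3, GADD45B, ZFP36, DUSP1 and DDIT3, were left out of that test and were higher by 0.797 to 4.986 (median 1.773), and all 14 by a median of 0.711 (median absolute deviation 0.386). A response to the handling of that tissue and a difference of that donor cannot be told apart, since both libraries share a replicate number. Without replicate 2 of both zones 3244 genes were higher and 2226 lower in LZ cells, against 3011 and 1782 with it.

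The follicular dendritic cell genes CLU, FDCSP and VCAM1 were high in the total GC libraries, with single-gene ranges of 3.02 to 4.44-fold over the 3 libraries. Expression by the GC B cells themselves is argued against by the separated zones, where the higher zone mean reached at most 0.0295 of the GC mean for any of the 3 genes. Collagen-producing fibroblasts are argued against by their summed collagen and proteoglycan transcripts, at 2.24 ± 0.626 TPM, at most 0.0365 of the CLU level in a library. The ratio of any pair of the 3 genes varied by at most 1.66-fold over the libraries, less than the single genes, so RNA of follicular dendritic cells carried along in varying amount may account for the pattern, although magnetic separation of B cells would be expected to remove most such cells. The zones were separated by another procedure than the GC libraries.

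T cell markers were also high in the total GC libraries. Expression of CD3D, CD3E, CD3G and CD2 by GC B cells is argued against by the zones, where the higher zone mean was at most 0.183 of the GC mean. The bound for these genes was looser than the 0.1 set for the follicular dendritic cell genes, which CD3E did not meet. For LCK and PDCD1, picked after their values were seen, the higher zone mean was at least 0.715 of the GC mean, so both may be expressed by the B cells. Of the 13 markers that rose 7 were under 0.1, and CD4, CD8A and SH2D1A lay between, at 0.424, 0.322 and 0.231. The ratio of any pair of the CD3 genes and CD2 varied by at most 1.496-fold over the GC libraries, where the single genes varied by 2.59 to 3.56-fold, as RNA of T cells carried along in varying amount would give, although magnetic separation of B cells would be expected to remove most such cells. A single lower share of B cells that raised T cell and follicular dendritic cell transcripts alike is argued against, since the ratio of CD3D to FDCSP varied by 3.256-fold. The levels of CD3D were 15.1 ± 6.70 TPM in GC and 0.315 ± 0.302 TPM in naive libraries.

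Other groupings of the same libraries into equal groups were counted for each comparison. Each of them mixes the 2 populations within its groups, which widens the spread there, so low counts were likely beforehand. For LZ against DZ, 1 of 35 groupings, the real one, gave as many genes (4793, the highest other 2). The zone libraries are paired, so the 35 groupings are not interchangeable and their share cannot exclude chance. The groupings that keep a pair together set differences between donors against each other. The 8 groupings that part all 4 pairs, as the real one does, are too few for a share under 0.05. Among them the highest other count was 1, and with the replicate block it was 0 against 6942. The 10 groupings of 3 against 3 libraries are too few for a share under 0.05. There 1 of 10 groupings, the real one, gave as many genes in each comparison. The real counts were 9284 for GC against naive, 8683 for memory against GC and 1718 for memory against naive, and the highest others were 1, 0 and 3.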

How the results depend on the processing

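The fits with voom on estimated reads, with rescaling without ribosomal RNA loci and nuclear mitochondrial copies, and without replicate 2 of both zones were chosen after seeing the data, and the other settings before the data were examined. No named gene turned its direction in a setting where it passed the threshold there or in the main fit. Lists were tested again by camera only with an estimated correlation, with the replicate block and after rescaling without immunoglobulin, mitochondrial and ribosomal protein genes. In LZ against DZ they were also tested without replicate 2 of both zones. No list turned its direction in these settings under the same rule, and the other settings were not tried with camera. A turn between values that both missed the threshold was not counted. Over the single settings 2787 values of named genes kept their side of the threshold, 51 lost it and 2 gained it, and 335 values of lists kept it, 56 lost it, 55 of these with an estimated correlation, and 9 gained it. With a 2-fold minimum, which by construction calls fewer genes, 2715 genes were higher and 1907 lower in GC than in naive cells, 2124 and 2032 in memory than in GC cells, 870 and 176 in memory than in naive cells, and 945 and 591 in LZ than in DZ cells. In memory against naive the lower genes numbered 196 without a filter, where more genes were tested, 646 under quantile normalization and 524 under median-ratio scaling, and the cause of the last was not tested. Leaving out each library there gave 811 (without naive replicate 1) to 1211 (without memory replicate 3) higher and 126 (without naive replicate 1) to 387 (without memory replicate 1) lower genes, with fewer samples in each fit. In the other comparisons every such count, and those with other pseudocounts, filters, scalings and fits, stayed within 1.5 times the counts in the report. The ratio of shared to expected calls with a 2-fold minimum was 4.66 for higher in GC and DZ cells, 1.01 for higher in GC and LZ cells, up from 0.68 to the level of independent lists, 0.53 for lower in GC and higher in DZ cells, and 2.64 for lower in GC and higher in LZ cells, and the cause was not tested. With a pseudocount of 0.1, which widens differences of low genes, the zone axis was at -1.373 for naive, 1.28 for GC, -1.174 for memory, 2.211 for DZ and -1.485 for LZ libraries. The replicate block, where the numbers pair the zones, gave 4309 higher and 2633 lower genes in LZ cells, 4761 of them shared with the unblocked fit, and beyond the immunoglobulin and plasmacytoid dendritic cell lists it changed no other call of a named gene or list there. Naive, GC and memory libraries share only a number, with residual correlations of same-numbered libraries from -0.073 to 0.031, and the block gave 5215 and 3636, 3847 and 4348, and 1174 and 217 higher and lower genes in GC against naive, memory against GC and memory against naive. In the last FCER2, BCL2A1 and BCL2L1 then missed the threshold, and glycolysis genes and myeloid markers passed camera, both at adjusted p = 0.0469. Without replicate 2 of both zones chromatin regulators, glycolysis and plasmacytoid dendritic cell markers passed camera at adjusted p = 0.0436, 0.0409 and 0.0367. Depth is known only as an estimate, so no limit can be given for genes listed at 0.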

Other observations

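The lists and genes in this part were described after their values were seen, and 0 explanations were tested for them. The methyltransferase gene EZH2, which silences differentiation genes in germinal centre B cells, was at 175 ± 3.37 TPM in GC libraries (n = 3) against 12.9 ± 1.19 TPM in naive libraries (n = 3), and at 163 ± 21.6 and 174 ± 17.9 TPM in LZ and DZ libraries (n = 4 each). Chromatin regulators as a list rose in 11 of 19 genes and fell in 5 in GC against naive cells, with the same counts adjusted over the list alone (camera in limma, adjusted p = 0.189). The members that rose include EZH2, EED, SUZ12 and DNMT1, which maintain silencing marks, and those that fell include DNMT3A, TET2 and TET3, which set or remove DNA methylation. In LZ against DZ cells DNMT3A, TET2 and TET3 were the 3 members of the list that rose, and 5 fell, among them DNMT1 and DNMT3B, also adjusted over the list alone (camera adjusted p = 0.157). Glycolysis genes rose in 11 of 18 cases and fell in 4 in GC against naive cells, also adjusted over the list alone (camera adjusted p = 0.158). GAPDH rose from 897 ± 186 to 3722 ± 229 TPM, while the glucose transporter genes SLC2A1 and SLC2A3 and the hexokinase gene HK2 were among those that fell.

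B cell receptor signalling genes fell in 8 of 19 cases and rose in 3 in GC against naive cells, also adjusted over the list alone (camera adjusted p = 0.198). The kinase genes SYK and LYN and the phospholipase gene PLCG2 rose, and the coreceptor gene CR2 and the kinase gene BTK fell. IRF4 and MYC, markers of activated light zone cells, were lower in GC than in naive cells, at 11.7 ± 2.44 against 72.3 ± 9.73 TPM and 29.6 ± 7.17 against 140.2 ± 65.3 TPM. Light zone markers rose in 5 of 16 cases and fell in 7 there, also adjusted over the list alone (camera adjusted p = 0.256). Plasma cell genes in LZ against DZ cells rose in 6 of 14 cases and fell in 3, against 6 and 4 adjusted over the list alone (camera adjusted p = 0.666). PRDM1 was at 49.2 ± 32.2 TPM in LZ and 5.54 ± 1.33 TPM in DZ libraries, while MZB1, JCHAIN and TNFRSF17 fell.

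Heat shock and handling stress genes and the myeloid and the erythroid and platelet markers gave no camera call in the 4 comparisons at the preset correlation, and neither did the epithelial markers in the 3 comparisons where they were tested. In LZ against DZ only 2 epithelial markers passed the filter on low values, too few for camera. In GC against naive cells heat shock and handling stress genes rose in 5 and fell in 4 of 13 cases, also adjusted over the list alone (camera adjusted p = 0.908). Myeloid markers rose in 1 of 7 tested genes and epithelial markers in 2 of 4, and of 3 tested erythroid and platelet markers 0 passed in limma, 0 by voom and 0 at an unadjusted p under 0.05, with the same counts adjusted over each list alone (camera adjusted p = 0.513, 0.403 and 0.351). In memory against GC cells the erythroid and platelet markers HBA1 and HBA2, near-identical copies, rose among the 3 tested and none fell, against 3 and 0 adjusted over the list alone (camera adjusted p = 0.197). The summed TPM of that list ran from 3.47 to 87.3 in the memory libraries and from 0.224 to 1.01 in the GC libraries.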
